A study of Mus musculus with 4 samples.

How the data were processed

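Total RNA from mouse knee articular chondrocytes infected with Ad-Epas1 or mock adenovirus was hybridised to 4 two-colour Agilent whole-mouse arrays. Per the labels, 0.2 µg of RNA was labelled with a low-input kit, mock RNA with Cy3 and Ad-Epas1 RNA with Cy5 on every array. Groups and replicate numbers were taken from the labels. Per the file headers, the 4 arrays lay on 1 slide and were read together, so no batch comparison between slides could be made. With the same dye orientation throughout, dye and infection cannot be told apart.

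Each deposited scanner file gave spot intensity on a linear scale (mean spot signal, local median background and processed signal in both channels), with flags for saturation, outliers and signal well above background. Per the file headers the images were read with Agilent Feature Extraction 9.5.3.1, while the submitters' processing notes name version 9.3.2.1. Per the file headers, the software's own log ratio is the log10 of processed Cy5 over processed Cy3 after background subtraction and dye normalisation. The authors' deposited series table held a linear ratio of Cy5 over Cy3 for 41174 probes. This was found by setting each column against the same array's log ratio (r = 0.988 to 0.999 across probes). Its column medians lay between 0.977 and 1.01, and how the authors made this table is not given in the sources used here. The file of array 1 had been re-saved by a spreadsheet, which rounded its signals and altered 47 gene names, so names were taken from another array's file of the same design.

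For the main analysis, mean spot and median background intensities were corrected with limma's normexp at an offset of 50. Log2 ratios of Cy5 over Cy3 were then normalised within each array by loess, with control spots and outlier-flagged spots at weight 0. Of 45018 spots, 1639 control spots were left out after normalisation, flagged spots were treated as missing and spots of 1 probe were averaged. A probe was kept when it was well above background in either channel on at least 2 of the 4 arrays, which left 29670 of 41174 probes. Probes were named through their RefSeq accession (22951 probes), their symbol (6659) or a unique synonym (3109) in a RefSeq gene table of assembly GRCm38.p6, and 8455 kept the name in the file. The probe with the highest mean intensity stood for each gene, provided that at least 2 arrays gave a usable value. Of the 20328 genes tested, 19789 had values on all 4 arrays. Probe positions are those in the files, per the file headers in build mm7. The files do not say whether a probe lies in a coding exon or a UTR.

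Mean log2 ratios were tested against 0, two-sided, with limma's lmFit and eBayes (limma 3.58.1, R 4.3.3, with data.table at version 1.17.8), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 24 gene lists were each compared with all other genes by limma's camera in its pre-ranked form on the moderated statistics, since some genes lack arrays, at a preset correlation of 0.01. They were also tested with a correlation estimated from the residuals and with fry, which asks whether a list moves one way without setting it against other genes. Both used the genes with values on all arrays. Members lacking an array, such as Mmp13, Rsad2, Ero1a and Ccl7, were therefore left out of these 2 tests. With an estimated correlation none of the 24 lists passed (adjusted p from 0.27 to 0.96, 3 lists at an unadjusted p under 0.05), while fry called 14. A gene saturated in a channel on all arrays, or not well above background there, is given as at least N-fold or with no fold. Such a bound is the mean of the brighter channel over that of the dimmer one after loess and Aquantile, and stays open to dye bias.

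The named genes were Epas1, all HIF-2α catabolic factors, and the 8 highest and 8 lowest called genes with the same sign on all 4 arrays that had a usable gene symbol. From each other list they included up to 3 called members with the largest ratio, or the member with the smallest p where none was called. This rule, the lists and the main alternatives were set before the data were examined. The alternatives covered the background correction, the dye normalisation, the filter on dim probes, the choice of probe, the variance model, the pairing by array and leaving out each array. Members without a probe of that name or below the filter, such as Gapdh, Tnf and Prg4, were not analysed here.

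The 2 samples of an array deviated together from their group means (r = 0.68 to 0.82 across genes, against -0.39 to -0.01 for samples on different arrays). They share spots and a hybridisation, so this does not show that they share a cell preparation. Deviations from a group mean cancel over the group, so values between arrays turn negative when those within arrays are positive. The ratio within each array had been set beforehand as the unit of the test.

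A limit of the background step was found after the data were seen. On arrays 1, 2 and 4 a total of 15 spot readings had a background more than 50 units above the signal. They widened the noise that normexp fitted, so that a dim spot at the 5th percentile in Cy5 was raised from 36.9 to 273 units on array 1 and from 45.8 to 300 on array 4, against 37.0 from 38.8 on array 3. In Cy3 such a spot was raised from 16.8 to 377 units on array 1 and from 20.2 to 95.9 on array 4. On array 2 the Cy5 value became 90.9, against 52.4 in a fit without those readings. Ratios of dim genes are therefore understated on arrays 1 and 4, and are open to the same effect on array 2. The main analysis was kept as designed, and a fit of normexp without those readings was added as an alternative. There Lcn2 gave 5.33 in place of 4.86, Mmp10 3.26 in place of 2.76, Egln3 3.14 in place of 2.72 and Cxcl2 4.02 in place of 3.40, and no named gene changed its call.

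The calculation was tested on simulated arrays with the real signal levels, the real spread of each probe, a curved dye bias and known changes, over 20328 genes. The simulated dye bias depended on intensity alone, noise was independent between genes, and far fewer genes changed than were called in the data. Readings with a background far above the signal were not simulated. The rates below hold for that setting only and do not give the share of false calls in the data. Of 100 genes simulated at 2-fold, 65 were recovered, with a median log2 ratio of 0.93 in the true direction. At 1.5-fold 27 of 100 were recovered, with a median of 0.54. A list of 20 further genes was simulated at 2-fold higher, and among all 108 calls 4 were false. In the fit without pairing by array none of the simulated changes passed.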

Results

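Gene expression was measured in knee articular chondrocytes, the matrix-producing cells of joint cartilage, taken from C57BL6 mice at day 5 of age. The cells were grown as a monolayer and infected at culture day 2 with an adenovirus carrying Epas1 (Ad-Epas1) or with a mock adenovirus. Epas1 encodes HIF-2α, an oxygen-regulated transcription factor. Infection lasted 2 h at a multiplicity of infection of 800, and RNA was taken after a further 24 h of culture. The series held 4 mock samples and 4 Ad-Epas1 samples, described as biological replicates, on 4 arrays. Each array carried mock RNA in Cy3 and the equally numbered Ad-Epas1 RNA in Cy5. The dyes were never exchanged, so every ratio below is open to a dye effect that these arrays cannot separate from the infection. The labels do not say whether the equally numbered samples came from 1 cell preparation. Between 23420 and 31575 of 41174 gene probes stood well above background in the mock channel, and between 22642 and 28906 in the Ad-Epas1 channel. Array 3 had the fewest in both channels. The number of arrays limits the precision of all values. Values are mean log2 ratios of Ad-Epas1 over mock ± SD over arrays, with n = 4 unless another n is given, and adjusted p-values are from limma.

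The first comparison asked which genes differed between Ad-Epas1 and mock chondrocytes. Genes of matrix breakdown, inflammation, antiviral defence and glycolysis were among those higher after Ad-Epas1, and genes of fat cells and of the cartilage matrix were among those lower. Among the highest ratios was Mmp3 (stromelysin-1, a matrix protease), at 5.28 ± 0.78, or 38.9-fold (adjusted p = 0.00016), with Cy5 saturated on 2 arrays. Prok2, a secreted chemokine-like peptide, was saturated in Cy5 on all 4 arrays and therefore at least 36.1-fold higher (adjusted p = 0.00071). The Prok2 mean was 4.53 without array 3, and its other probe gave 5.44 ± 0.51, so these values do not rank it against Mmp3. The iron-binding protein Lcn2 rose by 4.86 ± 0.80, the acute-phase protein Saa3 by 4.55 ± 0.31, and the chitinase-like protein Chil1 by 4.30 ± 0.36. The chemokine Cxcl1 was higher by 4.25 ± 1.06, Selenbp1 by 4.03 ± 0.23 and the interferon-induced Trim30a by 4.02 ± 0.68. Cy5 was saturated on 2 arrays for Cxcl1 and on 1 for Lcn2 and Chil1. Selenbp1 has a close paralogue, so its probe may not separate the pair. The adipokine Retn had the lowest ratio, at -2.59 ± 0.79, or 6.02-fold lower (adjusted p = 0.0014). It was followed by Fam180a at -2.28 ± 0.55, carbonic anhydrase Car3 at -2.23 ± 0.98, the matrix protein Abi3bp at -2.17 ± 0.49 and Gpd1, an enzyme of glycerol lipid synthesis, at -2.17 ± 0.58. Cobl at -2.15 ± 0.77, Itgbl1 at -2.02 ± 0.57 and the fat-cell hormone Adipoq at -2.01 ± 0.36 completed the lowest 8. The other probe of Car3 gave only -0.24 ± 0.24, and those of Abi3bp gave -1.05 ± 0.40 and -0.90 ± 0.81. Lcn2 and Trim30a stood well above background in mock on 3 of 4 arrays, and Car3 and Itgbl1 did so in Ad-Epas1 on 2 of 4.

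Of 20328 genes tested, 7335 changed at an adjusted p under 0.05, with 3706 higher and 3629 lower in Ad-Epas1. That balance depends on loess, since median centring gave 3280 higher and 901 lower. A change of at least 2-fold was found for 893 of them, 609 higher and 284 lower. At least 4-fold changes numbered 169 higher and 9 lower. Other probes of the changed genes had the sign of the chosen probe in 72.2% of cases, against 64.2% over all genes. Part of the count may therefore be specific to single probes. The median ratio of the other probes in that direction was 0.18, against 0.54 for the chosen probes. The chosen probes were the brightest and had passed the test, so that gap can come from the choice alone. The ratios of the 4 arrays correlated across genes at r = 0.65 to 0.83, where genes are not independent replicates. When the 8 channel samples were compared without regard to the array they shared, 693 genes changed, 511 of them at least 2-fold. Only 1 member each of the cartilage, cell cycle, apoptosis, ribosomal and adipocyte lists described below then passed. Leaving out array 1 gave 4424 changed genes and leaving out array 3 gave 4888. Some genes moved further in the scanner software's own log ratios, with 5.201 for Cxcl2, 4.47 for Mmp10, 4.15 for Egln3, 2.60 for Ch25h, 2.14 for Nos2, -1.86 for Panx3 and -3.24 for Itgbl1.

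Transcripts of the Epas1 gene were measured by 2 probes of 60 bases. The brighter probe lies on chromosome 17 from 85133910 to 85133969 (mouse build mm7) and has the sequence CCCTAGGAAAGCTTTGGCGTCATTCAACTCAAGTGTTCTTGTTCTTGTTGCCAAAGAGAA. It gave 0.79 ± 0.34, or 1.72-fold higher, with all 4 arrays between 0.48 and 1.26 (adjusted p = 0.0062). The call was lost without the pairing by array (adjusted p = 0.25). The other probe, on chromosome 17 from 85101159 to 85101218, gave 0.63 ± 0.30. Whether either probe lies within the part of Epas1 carried by the virus is not given in the sources used here. The probes therefore do not check the infection labels, and the values may describe the cells' own Epas1 transcript.

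**Figure D1:**
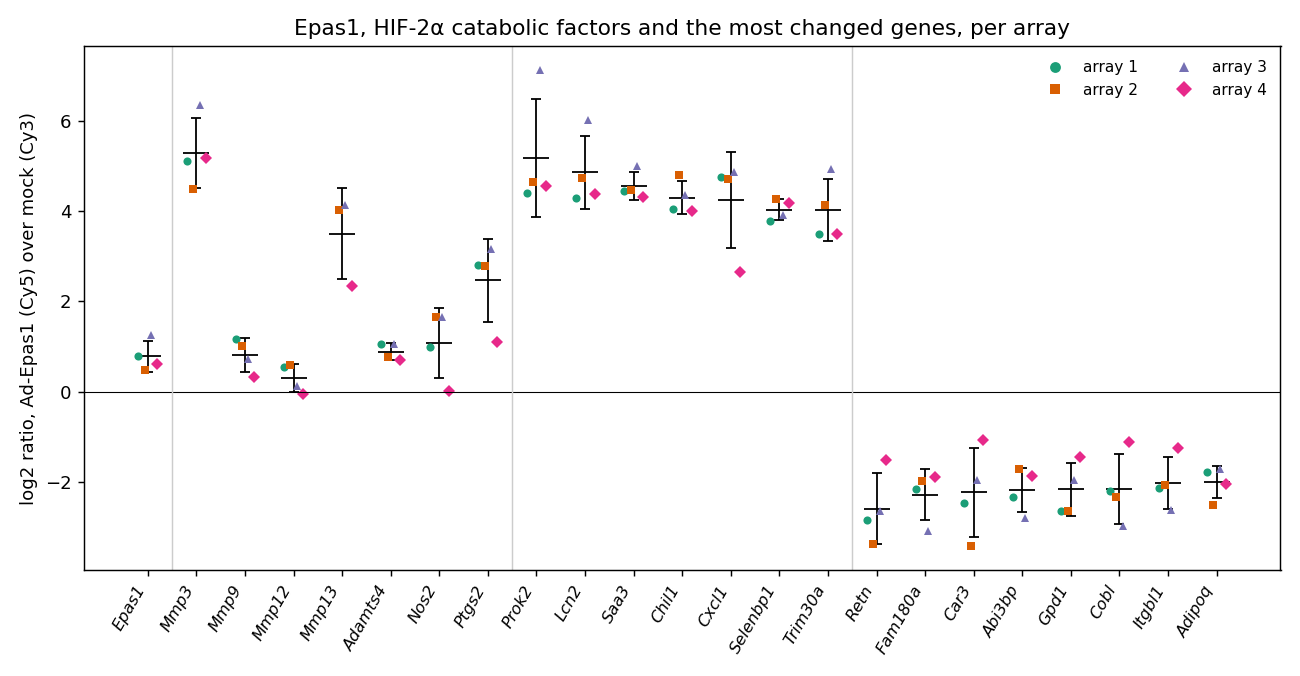
Log2 ratio of Ad-Epas1 (Cy5) over mock (Cy3) on each of the 4 arrays (coloured points, vertical axis) for Epas1, the HIF-2α catabolic factors, the other genes with the highest ratios and the 8 with the lowest. Black bars show the mean and whiskers the SD, and values run from 7.12 for Prok2 on array 3 to -3.43 for Car3 on array 2. Saturated spots are drawn at their recorded value.

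The next comparison concerned the cartilage-degrading factors known as HIF-2α targets in chondrocytes. Of the 7 measured, 6 rose and none fell (the same 6 adjusted over the list alone). Besides Mmp3 on chromosome 9 (7453874 to 7453933), the collagenase Mmp13 was 11.3-fold higher at 3.50 ± 1.00 (n = 3, Cy5 saturated on 1 array, chromosome 9 from 7280046 to 7280105). The prostaglandin synthase Ptgs2 rose by 2.46 ± 0.92, or 5.51-fold, and its other probe gave 1.77 ± 0.90. Nitric oxide synthase Nos2 was higher by 1.08 ± 0.77, the aggrecanase Adamts4 by 0.89 ± 0.19 and the gelatinase Mmp9 by 0.81 ± 0.37. Nos2 stood well above background on 2 arrays in mock and 3 in Ad-Epas1, and its call was lost without array 1, 2 or 3. Mmp12 gave 0.30 ± 0.32 and did not pass (adjusted p = 0.11), but passed as higher without array 4 (0.42, adjusted p = 0.048). All 7 passed there and after a trend on probe base composition was removed. The list as a whole was higher (median 1.08, adjusted p = 0.00013 with limma's camera at a preset correlation), but not with an estimated correlation (adjusted p = 0.35). The list lacked Mmp13 in that second test. Its median was 2.14 with the software's log ratios and 2.46 for the 5 members well above background in both channels on all arrays. Without saturated genes, which leaves out Mmp3 and Mmp13, it was 0.89. The list comes from published knowledge of HIF-2α in cartilage. Whether that knowledge drew on these samples is not given in the sources used here, so the list may not be independent evidence.

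Among 22 other matrix proteases, 3 rose and 3 fell, and the list showed no shift (adjusted p = 0.98). Its median was -0.03 and its mean 0.08. Stromelysin-2, Mmp10, was 6.79-fold higher at 2.76 ± 0.60, with mock well above background on 1 array. Adamts15 fell by 1.65 ± 0.64. Adamts5, the other main aggrecanase, gave 0.76 ± 0.35 at its brighter probe and -0.17 ± 0.41 at the other, and its call was lost when the probes were averaged. Of 12 protease inhibitors, 5 rose and 2 fell (5 and 3 adjusted over the list alone), without a shift of the list (adjusted p = 0.63). Without array 1 or 2 only 3 rose, and without array 4 there were 4 falls. Reck, a membrane-anchored inhibitor of matrix proteases, fell by 1.23 ± 0.24. Timp3 was called lower, but its Cy5 signal was saturated on all 4 arrays and its Cy3 signal on 2, so no fold is given. The Timp3 call was lost with the deposited series values (adjusted p = 0.058) and with median centring (adjusted p = 0.11).

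Transcripts of glucose metabolism and other known HIF targets were higher together. Of 20 glycolysis and HIF metabolic genes, 17 rose and none fell (19 adjusted over the list alone). The lactate transporter Slc16a3 was 5.69-fold higher at 2.51 ± 0.57 and glucose phosphate isomerase Gpi1 was 3.32-fold higher at 1.73 ± 0.30. The other probe of Gpi1 gave 0.19 ± 0.34. The glucose transporter Slc2a1 was saturated in Cy5 on all arrays and usable on 2, and was at least 2.95-fold higher (adjusted p = 0.0055). The list's median was 0.98 (adjusted p = 1.4e-09, and adjusted p = 0.27 with an estimated correlation). Of 24 HIF targets outside glycolysis, 17 rose and 1 fell (20 and 1 adjusted over the list alone). The oxidoreductase Ero1a was 9.72-fold higher at 3.28 ± 0.26 (n = 3, Cy5 saturated on 2 arrays), the prolyl hydroxylase Egln3 6.59-fold at 2.72 ± 0.24 (mock well above background on 2 arrays), and adrenomedullin, Adm, 4.43-fold at 2.15 ± 0.47 (n = 3). The median was 0.84 (adjusted p = 1.2e-07, and adjusted p = 0.27 with an estimated correlation). The 10 HIF pathway components showed no common shift (adjusted p = 0.98). Their median was -0.04 and their mean 0.08, with 3 higher and 2 lower. Hif1a rose by 1.10 ± 0.35 and Vhl by 0.80 ± 0.26. Hif1an was lower by -0.68 ± 0.37, while its other probes gave 0.12 and -0.03. Its call was lost without array 2 (adjusted p = 0.052) and when the probes were averaged (adjusted p = 0.16).

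Inflammatory genes formed a second group of large increases. Of 16 measured cytokines and chemokines, 11 rose and none fell (12 adjusted over the list alone). Cxcl2 gave 3.40 ± 1.80, ranging from 0.83 on array 4 to 4.91 on array 3, with mock well above background on 1 array. Ccl7 was 9.69-fold higher at 3.28 ± 0.33 (n = 3), and its other probe gave 2.26 ± 1.07. The median of the list was 1.79 (adjusted p = 7.2e-06, and adjusted p = 0.40 with an estimated correlation), and 1.13 without saturated genes. Of 14 NF-κB feedback genes, 12 rose and none fell (12 adjusted over the list alone). Nfkbiz rose by 2.61 ± 0.95, the mitochondrial superoxide dismutase Sod2 by 2.02 ± 1.15 and the adhesion molecule Icam1 by 1.79 ± 0.83 (other probe 1.11 ± 0.41). Their median was 1.15 (adjusted p = 1.9e-05, and adjusted p = 0.36 with an estimated correlation). On array 4 the median of the NF-κB list was 0.35, against 1.02 to 1.46 on the other arrays.

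Interferon-stimulated and antiviral genes were higher, with a median of 2.098. Of 21 measured, 20 rose and none fell (21 adjusted over the list alone). Viperin, Rsad2, was 23.8-fold higher at 4.57 ± 1.06 (n = 3, Cy5 saturated on 2 arrays), the oligoadenylate synthetase-like Oasl2 13.1-fold at 3.71 ± 0.71 and Ifi44 11.6-fold at 3.54 ± 0.56. Other probes were also higher but by less, with 1.12 and 0.78 for Rsad2 and 0.97 for Ifi44. The adjusted p of the list was 5.2e-14, and the adjusted p = 0.28 with an estimated correlation. Both cultures received adenovirus, and no probe known to measure viral load was found on these arrays.

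Cartilage matrix and chondrocyte identity genes were lower as a list. Of 22 measured, 11 fell and none rose (11 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.00011, and adjusted p = 0.36 with an estimated correlation). With median centring in place of loess, 5 fell and 3 rose, with a median of -0.15 (adjusted p = 0.017). Leaving out array 1, 2 or 3 left 7, 6 and 7 falls. Matrilin-1, Matn1, was 3.05-fold lower at -1.61 ± 0.40 and Matn3 2.09-fold lower at -1.06 ± 0.64. The Matn3 call was lost without array 2 or 3. Col11a1 was called lower, but its Cy5 signal was saturated on all 4 arrays, so no fold is given for it, and the call was lost with median centring (adjusted p = 0.11). Its unsaturated other probes gave -0.98 ± 0.51 and -1.08 ± 0.56. Type II collagen, Col2a1, gave -0.12 ± 0.63 (n = 3) with Cy5 saturated on 3 arrays, and its regulator Sox9 gave -0.07 ± 0.13. Neither passed. Without the genes saturated on any array, 9 of 18 members fell (adjusted p = 0.00031). Of 14 hypertrophy and mineralisation genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.079). It passed as lower without array 2 (adjusted p = 0.027) and with no filter on dim probes (adjusted p = 0.035). With median centring 3 fell and 1 rose, with a median of -0.02 (adjusted p = 0.058). The parathyroid hormone receptor Pth1r fell by 1.13 ± 0.15 and the phosphatase Alpl by 0.82 ± 0.32. Panx3 was called at -1.08 ± 0.84, with 0.02 on array 2, and lost the call without array 1 or 3. Among 16 fibroblast and dedifferentiation genes, 3 rose and 3 fell, without a shift of the list (adjusted p = 0.98). With median centring 6 rose and 1 fell, with a median of 0.53 (adjusted p = 0.16), and without array 4 there were 6 higher and 3 lower. Periostin, Postn, fell by 1.04 ± 0.10 (other probe -0.63 ± 0.26) and Pdgfrb by 0.95 ± 0.21, the latter not called with median centring (-0.54). Decorin, Dcn, gave 0.95 ± 0.41 at its brighter probe, saturated in Cy5 on 2 arrays, and 0.04 ± 0.55 at the other.

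**Figure D2:**
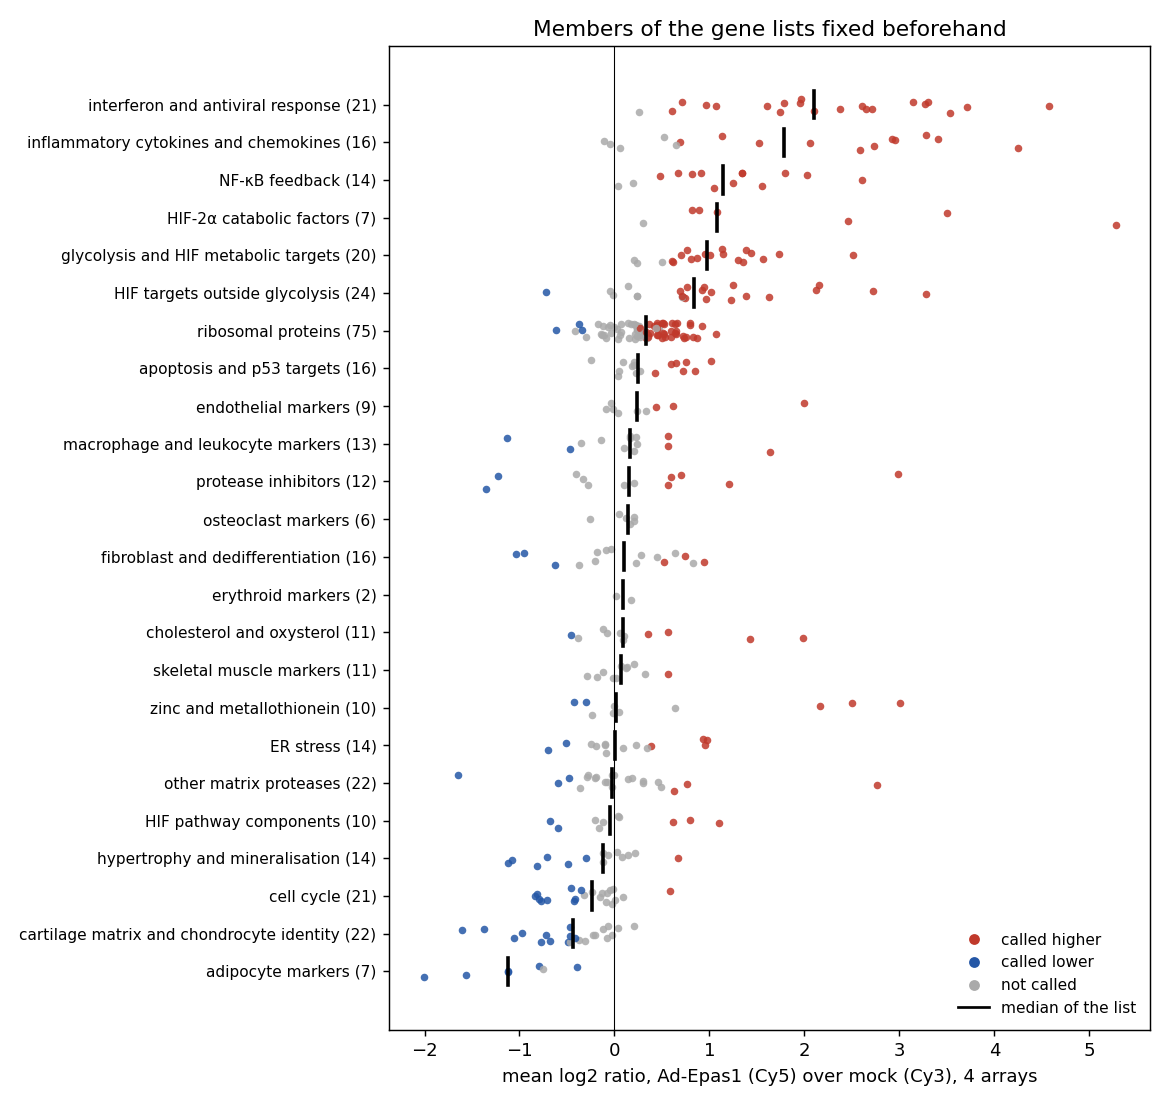
Mean log2 ratio of Ad-Epas1 over mock (horizontal axis) for each measured member of the 24 gene lists, with the number of members in parentheses. Red and blue points passed the test as higher or lower and grey points did not, and black bars mark each list's median, from 2.098 for interferon and antiviral genes to -1.12 for adipocyte markers. Vertical scatter within a list has no meaning.

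Cell cycle genes were slightly lower. Of 21 measured, 9 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.24 (adjusted p = 0.0011, and adjusted p = 0.35 with an estimated correlation). The proliferation marker Mki67 fell by 0.84 ± 0.02, the replication factor Mcm2 by 0.82 ± 0.25 and the checkpoint kinase Bub1 by 0.80 ± 0.14. Apoptosis and p53 target genes were higher in 7 of 16 cases and lower in none (7 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.0030, and adjusted p = 0.27 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 1.02 ± 0.15, Fas by 0.85 ± 0.47 and Bax by 0.75 ± 0.06. The Fas call was lost without array 2, where 3 of 15 members of the list rose, and 4 of 16 rose with the software's log ratios. Ribosomal protein genes shifted upwards by a small amount. Of 75 measured, 37 rose and 3 fell (41 and 4 adjusted over the list alone), with a median of 0.33 (adjusted p = 1.1e-06, and adjusted p = 0.28 with an estimated correlation). Rpl5 rose by 1.07 ± 0.32, Rpl17 by 0.92 ± 0.11 (n = 3) and Rps6 by 0.87 ± 0.14. Ribosomal protein genes have many near-identical pseudogenes, so single members are uncertain, and without array 1 the count was 24 higher and 0 lower. With median centring the medians were -0.03 for the cell cycle, 0.64 for the apoptosis and 0.80 for the ribosomal list, each still past the threshold. Only 4 cell cycle genes fell in that setting, and 1 rose.

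The ER stress list gave 4 higher and 2 lower genes of 14 and no shift (adjusted p = 0.67). The chaperone Hspa5 rose by 0.97 ± 0.28, Sdf2l1 by 0.95 ± 0.17 and Dnajb9 by 0.93 ± 0.20. Of 10 zinc and metallothionein genes, 3 rose and 2 fell, without a shift of the list (adjusted p = 0.58). The falls did not hold, with 0 or 1 left when any array was left out. The metallothionein Mt2, saturated in Cy5 on all arrays, was at least 8.05-fold higher (adjusted p = 0.0020), Mt1 was 5.66-fold higher at 2.50 ± 0.38 and the zinc importer Slc39a8 4.47-fold at 2.16 ± 1.29 (other probe 1.47 ± 1.59). Cholesterol and oxysterol genes gave 4 higher and 1 lower of 11 (4 and 2 adjusted over the list alone), with no shift (adjusted p = 0.58), and 1 rose without array 1 or 2. The oxysterol hydroxylase Cyp7b1 gave 1.99 ± 1.32 and was not called without array 1, 2 or 3. Cholesterol 25-hydroxylase, Ch25h, rose by 1.42 ± 0.72, with mock well above background on 2 arrays. Rora gave 0.57 ± 0.31, and its call was also lost without array 1, 2 or 3. Its other probes gave 0.06 and 0.41, and the call was lost when the probes were averaged (adjusted p = 0.14).

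Markers of other cell types that a cartilage digest could hold were examined in the same way. All 7 adipocyte markers had negative ratios, and 6 fell (6 adjusted over the list alone), with a median of -1.12 (adjusted p = 0.00011, and adjusted p = 0.28 with an estimated correlation). With median centring 3 fell and the median was -0.62. Besides Adipoq, the complement factor Cfd fell by 1.57 ± 0.54 and the fat-cell regulator Pparg by 1.12 ± 0.32. Macrophage and leukocyte markers went both ways, with 3 of 13 higher and 2 lower (adjusted p = 0.58), or 1 and 1 without array 1. Cd68 rose by 1.64 ± 0.75 and C1qb by 0.57 ± 0.31, while the lysozyme Lyz2 fell by 1.13 ± 0.40. The other probe of Lyz2 gave -0.45 ± 0.53, and the call was lost with it (adjusted p = 0.078). The C1qb call was lost without array 1. Of 9 endothelial markers, 3 rose (adjusted p = 0.17). The VEGF receptor Flt1, itself a HIF target, was 4.00-fold higher at 2.00 ± 0.69 at its brighter probe and gave 0.65 ± 0.18 at the other. Cldn5 rose by 0.62 ± 0.26 and Vwf by 0.43 ± 0.19, and the Vwf call was lost without array 1, 3 or 4. The other probes of Vwf gave 0.18 and 0.06. Its call was also lost when the probes were averaged (adjusted p = 0.088) and with median centring (adjusted p = 0.053). Mylpf, at 0.56 ± 0.35, was the only one of 11 skeletal muscle markers to pass (0 adjusted over the list alone, list adjusted p = 0.68), and it did not pass without array 1 or 4. No member of the osteoclast or erythroid lists passed in the main analysis. Ctsk, at -0.25 ± 0.18, had the smallest p of 6 osteoclast markers (list adjusted p = 0.67), and Slc4a1, at 0.18 ± 0.11, that of 2 erythroid markers (list adjusted p = 0.68). Slc4a1 passed as higher with the software's log ratios (0.47, adjusted p = 0.041) and Ctsk as lower with array weights (-0.30, adjusted p = 0.047). Another osteoclast marker passed as higher with the software's log ratios.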

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

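The tests of leukocyte markers and of the spread among adipocyte markers, and the splits counted for changes of at least 2-fold, were chosen after the values had been seen. So were the 2-fold limit for reporting a control probe and the allowance for adipocyte markers that other cells make, which was added once Fabp4 was seen to fall least. The other tests in this part were written down first.

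Among 75 named genes with values on all 4 arrays, 6 had 1 array far from the other arrays, where chance gives about 1 in 20. Array 4 stood low for 4 of them. Sod2 was 0.31 there against 2.38 to 2.77 on the other arrays, Icam1 0.55 against 2.11 to 2.36, Cxcl1 2.65 against 4.70 to 4.87 and Adamts5 0.25 against 0.86 to 0.97. The software's own log ratios gave 0.23 for Sod2 and 0.59 for Icam1 on array 4. By the same log ratios the median of the NF-κB list was 0.52 on array 4 and 1.27 to 1.76 elsewhere, that of the cytokine list 1.10 and 2.34 to 3.12, and that of the HIF-2α catabolic list 0.93 and 2.48 to 3.05. The glycolysis list (0.69 and 0.99 to 1.18) and the interferon list (2.17 and 2.50 to 3.04) were lower there by less. The SD of ratios across genes was also smallest on array 4 (0.47, against 0.55 to 0.67). Genes called higher had their lowest mean there, at 0.57 against 0.73 to 0.87. In the main log ratios HIF targets outside glycolysis had a median of 0.41 there against 0.88 to 0.97. Adipocyte markers gave -0.66 against -0.91 to -1.29, but cell cycle genes -0.23 against -0.16 to -0.38. Smaller ratios on array 4 were not limited to inflammatory and catabolic lists. These differences were not tested. Prok2 was high on array 3, at 7.12 against 4.39 to 4.64, with Cy5 saturated on every array. Bax was low on array 1, at 0.66 against 0.78 to 0.79.

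Outside the gene probes, 1 control probe named for the adenoviral E1A gene gave a log2 ratio of 1.20 ± 0.13 (SD, n = 4), higher in Ad-Epas1 on every array. It was well above background in both channels, with median Cy5 signals of 1217 to 6950 and Cy3 signals of 328.6 to 1262 over its 32 spots. Its signals were higher on arrays 1 and 2 (Cy5 6950 and 5270, Cy3 1125 and 1262) than on arrays 3 and 4 (Cy5 1217 and 1612, Cy3 328.6 and 386.2). Another 9 control probes with E1A names gave between -0.03 and 0.34. Whether this probe reads added control RNA or RNA of the vector is not given in the sources used here, so the value is not taken as a measure of viral load. The scanner software's slope of observed on expected log ratios for added control RNA lay between -0.08 and -0.03. The ratios expected of such RNA were therefore not seen, but this does not show what the probe reads.

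The number of changed genes was set against other ways of dividing the samples. Turning the sign of the ratios allows 8 arrangements, too few for a share under 0.05. The real arrangement called 7335 genes, 893 of them at least 2-fold, and the highest of the others called 0. In the fit without pairing, 1 of the 35 splits of the 8 channel samples, the real one, gave as many as 693 genes and the highest other split gave 151. For changes of at least 2-fold, 1 of 35 gave as many as 511, and the highest other split gave 133. These splits ignore that samples on 1 array belong together, so they speak only for the fit without pairing, and the real split is also the split between dyes. A dye effect tied to single probes was tested on other probes of the same genes. Of 396 such probes, 83.3% had the sign of the chosen probe, against 64.2% over all genes, changed ones included. This fell short of the 90% set beforehand, so such a dye effect may account for part of these genes. Their median ratio in that direction was 0.49 against 1.31 for the chosen probes. The chosen probes were the brightest and had passed the 2-fold limit, so that gap can come from the choice and decides nothing. After removing each array's trend on the base composition of the probes, 87.9% of the 893 genes were still called with at least a 2-fold change, also short of 90%. A dye effect shared by a whole transcript cannot be told apart from the infection, since 0 arrays had the dyes exchanged.

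Interferon and antiviral genes were higher by a median of 2.098. Leukocytes carried into the Ad-Epas1 cultures would bring all their abundant transcripts. The 13 leukocyte markers had a median of 0.16 and ran from -1.13 (Lyz2, -0.45 at its other probe) to 1.64 (Cd68), all below 2.098. Several were dim, and ratios of dim genes are understated on arrays 1 and 4, so that median cannot decide the question. Those well above background in both channels on all arrays were Cd68 (1.64), C1qb (0.57), Cd74 (0.56), Cd14 (0.16) and Fcer1g (-0.47). These values argue against leukocytes as the source of the whole shift, but not of a part of it. A dye effect of single probes is also disfavoured, since 92.9% of 14 other probes of the list's genes, from 9 genes, were higher in Ad-Epas1, although by less (median 0.87 against 1.97 for the chosen ones). A difference in dose or preparation between the vectors stays open, because no probe known to read the vector was available to set against the median of 2.098. A response to Epas1 itself remains a hypothesis beside it, and the design cannot separate them.

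The fall of the adipocyte markers (median -1.12) may reflect fewer fat cells in the Ad-Epas1 cultures or lower transcription within them. Among the 4 markers well above background in both channels on all arrays, the largest fall (Adipoq) exceeded the smallest (Fabp4) by a log2 difference of -1.22 ± 0.39, with every array between -1.60 and -0.81. The 2 genes were picked as the extremes of these markers, and other probes of Fabp4 gave -1.195 and -0.81. The difference met the condition first written for excluding a lower cell share. However, other cells also make Fabp4, which keeps that explanation open. Other probes of the list's genes were lower in 100% of cases, though only 3 such probes from 2 genes existed, too few to exclude a dye effect. A response to Epas1 within fat cells was not tested.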

How the results depend on the processing

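The fits without saturated probes and without outlying background readings were chosen after seeing the data. The base composition test above was written down first, but its fit was not among the settings planned for this part. Changed genes numbered 4181 with median centring, 693 with no replicate block (the array pairing ignored) and 4424 to 6260 when 1 array was left out, against 7335. Changes of at least 2-fold numbered 1743 with the Feature Extraction log ratio, 1718 with the series table, 511 with no replicate block and 787 to 1119 without 1 array, against 893. The cause was not tested. Median centring moved the share of higher calls from 50.5% to 78.5% and the median of all genes to 0.11, so its list shifts are relative to that. At 2-fold or more the share of higher calls was 68.2%, against 88.3% with median centring, 53.6% with the Feature Extraction log ratio and 55.5% with the series table. Without outlying background readings 7943 genes changed, 1112 of them at least 2-fold, with 7190 and 892 shared with the main calls. Without saturated probes the counts were 7158 and 809. Epas1 kept its sign in all settings and lost its call with no replicate block (0.79, adjusted p = 0.25). Of 24 lists, 11 passed in the main analysis, 11 or 12 in each of the gene-level settings, 14 with fry and 0 with camera at an estimated correlation, where 4 arrays leave few degrees of freedom. The added lists were hypertrophy (without array 2, or with no filter on dim probes) and cholesterol (median centring). No list that passed changed direction. Correlations within lists were estimated at 0.57 for the cytokine, 0.49 for the NF-κB, 0.45 for the HIF-2α catabolic and 0.38 for the interferon list. These lie above the preset 0.01, so the p-values of these lists at the preset correlation may be too small. The estimate was lower for other lists, such as 0.04 for HIF targets outside glycolysis and -0.05 for the apoptosis list. Among 83 other named genes, no sign turned and 37 kept their call or lack of it in the settings counted gene by gene, with most losses under no replicate block. That count leaves out the fits without saturated probes and after a base composition trend. Aquantile after loess leaves the ratios as they are and tests nothing. Signal over background limits the dim genes: median spot signals were 268 to 356 units in Cy3 and 503 to 608 in Cy5, over backgrounds of 49.0 to 59.0. Of 284 genes at least 2-fold lower, 21 were saturated in Cy5 on all arrays, and their falls can come from that.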

Other observations

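The gene groups in this part were chosen after the values of some of their members had been seen, so their tests describe these arrays only. Beyond single acute-phase proteins, 15 of 19 acute-phase and complement genes were higher in Ad-Epas1 and none was lower, with a median of 1.30 (adjusted p = 1.3e-08 with camera over these 4 groups, and adjusted p = 0.21 with an estimated correlation). Complement factor Cfb rose by 3.05 ± 0.86 (SD, n = 4), haptoglobin, Hp, by 2.89 ± 0.88 and complement C3 by 2.39 ± 0.21. The antigen presentation group rose in all 12 measured members, with a median of 2.01 (adjusted p = 1.2e-08, and adjusted p = 0.16 with an estimated correlation). Among these, the immunoproteasome subunit Psmb8 rose by 2.62 ± 1.11, beta-2 microglobulin, B2m, by 2.21 ± 0.22 and the peptide transporter Tap1 by 1.51 ± 0.54.

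Iron-handling genes moved in both directions, with 5 of 15 higher and 4 lower and no common shift (adjusted p = 0.92). The ferritin heavy chain Fth1, which stores iron, rose by 2.60 ± 0.81 and the light chain Ftl1 by 0.98 ± 0.13. The metalloreductase Steap4 was higher by 3.19 ± 1.30, while the iron exporter Slc40a1 fell by 1.98 ± 0.65 and the ferric reductase Cybrd1 by 1.67 ± 0.51. Small leucine-rich proteoglycans, matrix proteins that bind collagen, also went both ways, with 2 of 10 higher and 4 lower (adjusted p = 0.45). Asporin, Aspn, fell by 1.72 ± 0.30, osteomodulin, Omd, by 1.70 ± 0.85 and osteoglycin, Ogn, by 1.59 ± 0.73, whereas Podn rose by 0.70 ± 0.07.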
